A study of Nicotiana benthamiana with 6 samples.

How the data were processed

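The 6 libraries were made from total RNA of scion leaves with a plant RNA column kit and an NEB library kit, per the labels' protocols. Tomato rootstock seedlings aged 2 to 3 weeks had been joined to scions aged 3 to 5 weeks and grown at 25 °C with 12 hours of light, per the labels. Reads without a place on the Nicotiana benthamiana genome were mapped by the authors to the tomato genome SL3.0, per the labels' protocols. The aligner, its settings, the annotation release and the use of strand are not given in the sources used here. A table for each library was matched to its sample by the sheet name, which holds the sample's title.

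The deposited tables list the same 33925 genes with coordinates, reads and normalized values. Whole-number counts of reads per gene, total and uniquely placed, are deposited by the authors with no normalization, and gene reads include introns. In the deposited tables RPKM equals exon reads over exon length and a constant for each library. That constant was larger than the reads on genes, so the difference was taken as reads outside genes. TPM in the deposited tables is a share of each library's length-scaled exon reads and follows from exon reads and exon length. In the table of Dro141TX replicate 1 the headings from the exon reads on were shifted by 1 column, and exon reads were taken from the column from which RPKM and TPM could be recomputed. Rows without a gene name numbered 0. A total of 66 identifiers lie on another chromosome than their number says, and the chromosome of the files is given.

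Genes were compared on total reads per gene with edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr, quasi-likelihood F test, Benjamini-Hochberg adjusted p under 0.05), as Dro141TX minus Maxifort over all 6 libraries with no block. CPM values are scaled by TMM, and the SE of a log2 fold change is its size divided by the square root of F. The test was run on counts simulated from the means and library sizes of this comparison, with 100 of 10208 genes changed 2-fold and 100 changed 4-fold. It recovered 47% of the former and 99% of the latter, and made 17 false calls, 10.4% of all calls, above the nominal rate. The changed genes were all drawn from those with a mean of at least 50 reads, so recovery at fewer reads was not measured. The biological coefficient of variation was 22.0%. A count of 0 is given with a floor of 3 counts, which is 0.361 to 0.591 CPM in a single library. Floors and counting intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

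Lists of related genes were fixed before the data were examined, as were the main tests and most alternatives. The files pair only 114 identifiers with a symbol and hold no descriptions, so 9 lists were matched by identifier, recalled without a table to check them against. Lists defined by descriptions alone (disease resistance receptors, WRKY factors, redox enzymes, heat shock proteins, ribosomal proteins, root markers, ribosomal RNA and organelle genes) were not matched and are not analysed here. The 6 lists with at least 5 tested members were tested with camera in limma 3.58.1 at an inter-gene correlation of 0.01, with an estimated correlation and fry beside it. Groups of genes with a symbol were put together after their values were seen. Shares of reads and numbers of detected genes were compared with 2-sided exact permutation tests.

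The rule for named genes took the 10 genes of highest mean RPKM, the 10 largest called changes in each direction without overlap between groups and with at least 10 reads on average, up to 3 called members of each list (or its best member), and the 5 best covered genes detected in 1 group only. Most of these have no symbol, so only the 2 largest rises and the 2 largest falls are printed as identifiers and the rest are summarised. Called genes with a symbol, of which some are not reported here, and GAI, TD2, psbZ, RBCS-1, FRK2, CHI3 and CHI9, were named after their values were seen. Genes with a symbol and 0 reads numbered 21.

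Alternatives were DESeq2 1.42.0, its size factors in edgeR, library size only, other filters, unique reads, limma on log2(RPKM + 0.1) and log2(RPKM + 1) for genes with an RPKM of at least 0.5 in 3 libraries, other thresholds, a replicate block and leaving out each library. Exon reads only, equal depth and removal of the trend against exon length were added after seeing the data. Replicates of a group differed by more than counting noise, with a chi-square per degree of freedom of 10.1 to 43.4, so no library was counted as a copy of another.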

Results

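RNA was sequenced from scion leaves of Nicotiana benthamiana, a tobacco relative widely used as a host for plant viruses, grafted on tomato rootstocks. The rootstocks were Maxifort and Dro141TX, with 3 libraries each. Reads that had found no place on the scion's own genome were placed on the tomato genome, build SL3.0, to look for rootstock transcripts in the scion. The deposited tables list 33925 tomato genes on chromosomes 1 to 12, of which 18419 had at least 1 read in some library. Reads on tomato genes came to 6657055, 6806270 and 8307098 in Maxifort replicates 1, 2 and 3, and to 7152252, 7091533 and 5075947 in Dro141TX replicates 1, 2 and 3. The labels do not say whether the libraries of a group came from separate plants, so p-values measure the spread between these samples, which may be technical. The files hold no sequences or mismatch counts, so a read listed on a tomato gene is not shown here to come from the rootstock.

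The first question was which tomato genes the scion leaf reads lay on, on each rootstock. Genes of leaf photosynthesis led in both groups. The 3 genes RBCS-1, RBCS-2A and RBCS-3B, which code for the small subunit of Rubisco, the carbon-fixing enzyme, took 17.2% ± 1.97 of gene reads in Maxifort scions and 17.1% ± 1.80 in Dro141TX scions (SD, n = 3). RBCS-2A (Solyc03g034220.3, chromosome 3, 5956428 to 5958862, 4 exons) had the highest mean RPKM of all listed genes, 106847 ± 4757 on Maxifort and 86424 ± 15307 on Dro141TX. RBCS-3B (Solyc02g085950.3, chromosome 2, 49352761 to 49353728, 3 exons) followed with 36575 ± 2482 and 25056 ± 3308. The constant that RPKM divides by includes reads outside genes, 23.2% on Maxifort and 39.0% on Dro141TX. This pulls RPKM down on Dro141TX relative to Maxifort, so these values do not compare the groups. PSBO (Solyc02g065400.3, chromosome 2, 37141474 to 37144354, 2 exons), a subunit of the oxygen-evolving complex of photosystem II, was also among the 10 genes with the highest mean RPKM, at 7880 ± 416 and 9237 ± 3085. The other 7 carry no symbol in the files.

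The 10 genes with most reads together took 31.7% ± 3.06 of gene reads on Maxifort and 32.2% ± 2.46 on Dro141TX. The list of conserved housekeeping genes took 0.652% ± 0.117 on Maxifort and 0.434% ± 0.0275 on Dro141TX, with every Maxifort library above every Dro141TX library. The list of ethylene synthesis and signalling, the hormone of ripening and stress, took 0.0179% ± 0.00111 and 0.0250% ± 0.00333, with every Dro141TX library above every Maxifort library. Both gave a 2-sided exact permutation p of 0.1, the smallest that 3 against 3 allows, and 0.4 after adjustment over 8 tests. For the photosynthesis list, 18.3% ± 2.02 and 18.0% ± 1.85 of reads, and for the 3 RBCS genes, the exact p was 1. Reads of RNA silencing genes (0.0742% and 0.0652%), jasmonate and wound genes (0.0501% and 0.0684%) and salicylic acid genes (0.0240% and 0.0261%) gave exact p-values of 0.4, 0.4 and 0.7. On summed TPM in place of reads the housekeeping share was 0.470% on Maxifort and 0.312% on Dro141TX.

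**Figure D1:**
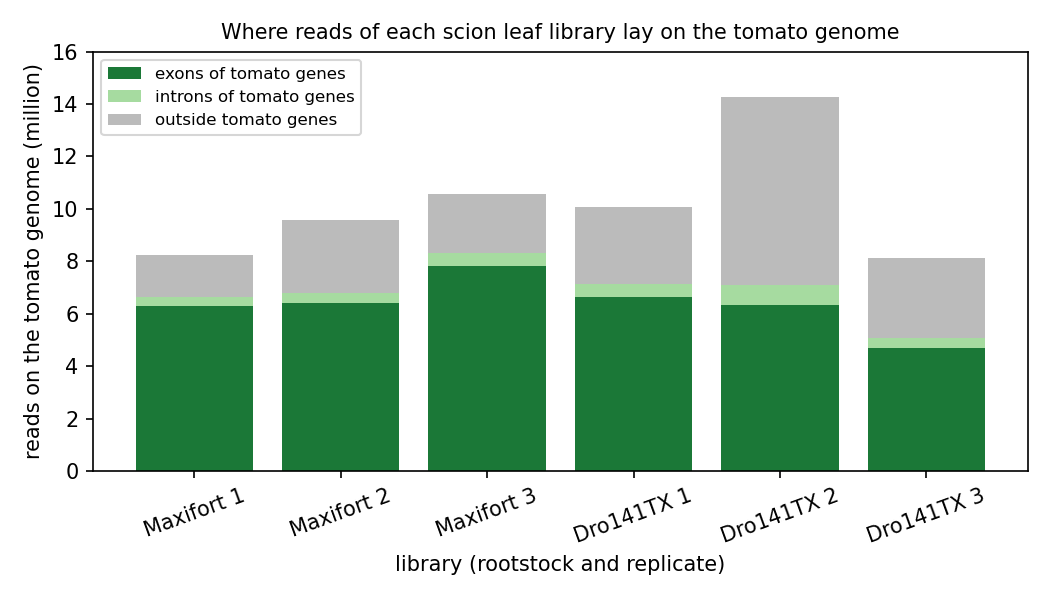
Bars show, for each library, on an axis in 1e6 reads, the reads that lay on exons and on introns of the listed tomato genes. The last part is reads taken as outside these genes, the RPKM constant less the gene reads. Their share was 19.4%, 28.8% and 21.4% in the Maxifort libraries and 28.9%, 50.4% and 37.6% in the Dro141TX libraries.

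The main comparison asked which tomato genes differed in read number between scions on Dro141TX and on Maxifort. Of 10448 genes tested, 1097 were higher and 1075 lower on Dro141TX (edgeR, quasi-likelihood test, adjusted p under 0.05), and 693 of the higher and 560 of the lower ones differed by at least 2-fold. The largest rises among genes with a symbol were in CHLN, the nicotianamine synthase that makes a metal chelator, in NAP1, a NAC transcription factor linked to leaf senescence, and in MTA, followed by a second such factor, NAP2. CYP707A1, which breaks down abscisic acid, and FLACCA, which activates the last enzyme of its synthesis, rose, while NCED2, named for an earlier step of its synthesis, fell. Among the genes that fell were XTH1, a cell wall xyloglucan enzyme, and SAM3, an S-adenosylmethionine synthetase.

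CHLN (Solyc01g100490.3, chromosome 1, 90378790 to 90379743) rose from 13.2 ± 10.3 to 119 ± 84.6 CPM (reads scaled to a common library size, SD, n = 3), a log2 fold change of 3.19 (SE 0.58, edgeR adjusted p = 0.00834). It was 2.44 without Dro141TX replicate 3 and 4.02 without Maxifort replicate 2, and did not pass without Maxifort replicate 3. NAP1 (Solyc05g007770.3, chromosome 5, 2229594 to 2232225) rose from 0.481 ± 0.285 to 4.02 ± 1.45 CPM, a log2 fold change of 3.06 (SE 0.49, edgeR adjusted p = 0.00564). NAP2 (Solyc04g005610.3, chromosome 4, 405052 to 406940) rose by 2.00 on the log2 scale (SE 0.41). MTA (Solyc04g058150.3, chromosome 4, 55185933 to 55187115) rose from 5.83 ± 3.32 to 35.0 ± 12.1 CPM, a log2 fold change of 2.59 (SE 0.40).

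In the group of abscisic acid and carotenoid genes with a symbol, 2 of 7 tested members rose, 1 fell and 4 did not pass. CYP707A1 (Solyc04g078900.3, chromosome 4, 63660433 to 63663805) rose from 5.20 ± 0.771 to 14.1 ± 1.25 CPM, a log2 fold change of 1.43 (SE 0.23, edgeR adjusted p = 0.00549). FLACCA (Solyc07g066480.3, chromosome 7, 68024899 to 68037948) rose from 14.5 ± 3.03 to 37.5 ± 6.26 CPM, a log2 fold change of 1.38 (SE 0.22). NCED2 (Solyc08g016720.1, chromosome 8, 8729953 to 8731698), named for a 9-cis-epoxycarotenoid dioxygenase of abscisic acid synthesis, fell by 1.22 on the log2 scale (SE 0.38). Its log2 fold change was -1.20, just short of the threshold, on uniquely placed reads. It did not pass when any 1 of the 6 libraries was left out, and was -0.74 without Maxifort replicate 2.

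Photosynthesis symbols went both ways, with 1 of 10 tested members higher, 1 lower and 8 not passing. The called share over all tested genes was 20.8%, and this group lay close to it. PSBR (Solyc07g066310.3), a small photosystem II protein, rose from 1993 ± 371 to 3729 ± 475 CPM, a log2 fold change of 0.90 (SE 0.22). CAB13 (Solyc12g011450.2), a chlorophyll-binding antenna protein, had a log2 fold change of -0.72 (SE 0.22), and one of -0.71, just short of the threshold, on uniquely placed reads. Its call held without Dro141TX replicate 2 and was lost when any other library was left out. RBCS-2A had a log2 fold change of 0.03 (SE 0.34), RBCS-1 of 0.36 (SE 0.28), RBCS-3B of -0.22 (SE 0.31) and PSBO of 0.53 (SE 0.27), none past the edgeR threshold. The signs of RBCS-1 and RBCS-2A turned to -0.01 and -0.32 on log2(RPKM + 0.1), a scale on which the median over all genes was -0.35. psaJ, a photosystem I subunit gene usually found on the plastid genome and listed here on chromosome 1 (76555113 to 76555244), rose from 11.7 ± 5.05 to 27.3 ± 1.21 CPM, a log2 fold change of 1.24 (SE 0.28). It was 1.25 on uniquely placed reads and 0.50, no longer past the threshold, with the exon-length trend removed. Another gene of this kind, psbZ, had a log2 fold change of 1.30 (SE 0.46) and did not pass (edgeR adjusted p = 0.0695), and one of 0.12 on uniquely placed reads.

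HSC80 (Solyc07g065840.2), a cytosolic chaperone of the HSP90 family, fell from 392 ± 96.6 to 202 ± 17.9 CPM, a log2 fold change of -0.96 (SE 0.21). The cyclophilin gene CYP (Solyc01g111170.3) rose from 489 ± 20.1 to 935 ± 188 CPM, a log2 fold change of 0.93 (SE 0.20), and of 0.69, just short of the threshold, with the exon-length trend removed. SAM3 (Solyc09g008280.2) fell from 835 ± 78.6 to 402 ± 79.0 CPM, a log2 fold change of -1.06 (SE 0.20), and on uniquely placed reads the value was -1.52 and did not pass. Other symbols that fell were XTH1 (-1.30), CITRX (-0.94), a thioredoxin that binds the resistance protein Cf-9, ODC (-0.85), the ornithine decarboxylase of polyamine synthesis, LCA1 (-0.80), a calcium pump, MSI1 (-0.80), a chromatin protein, and PGH1 (-0.60), an enolase, all as log2 fold changes. OPR3, an enzyme of jasmonate synthesis, rose by 0.75. Of 19 alternative settings, LCA1 passed in 7, PGH1 and OPR3 in 12, CITRX and MSI1 in 14, and XTH1 and ODC in 18. In all, 22 of the 63 tested symbols passed, 11 higher and 11 lower.

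**Figure D2:**
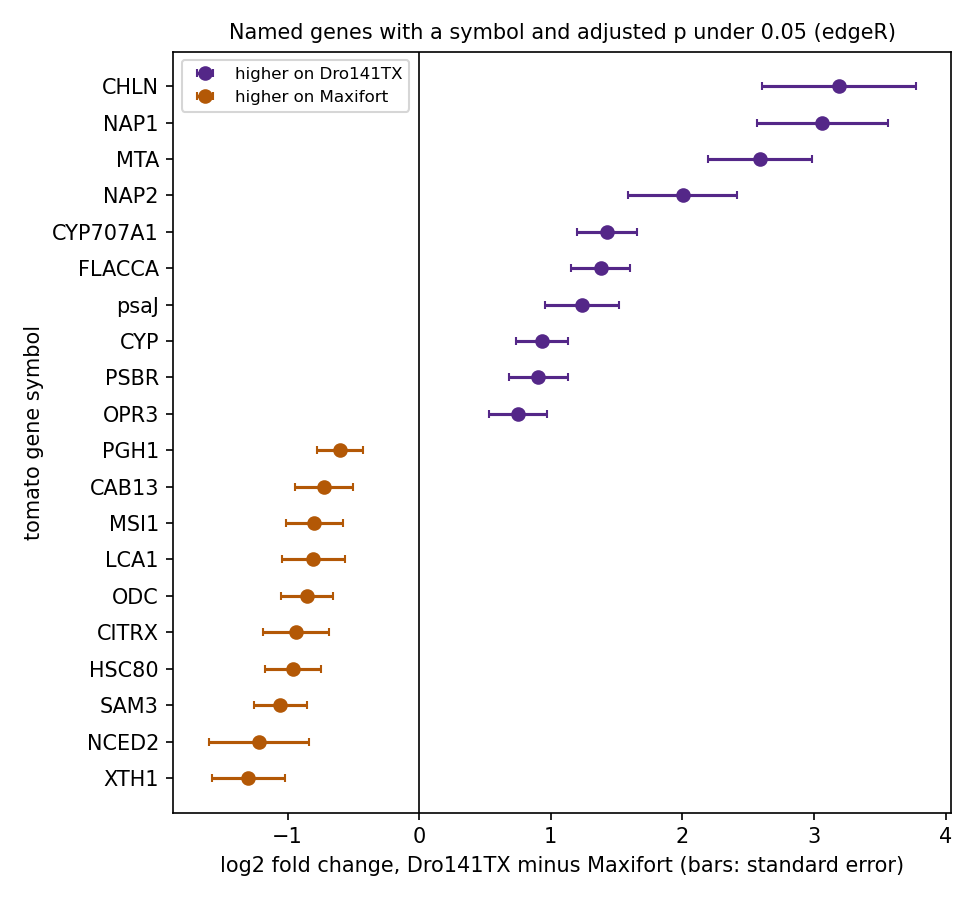
Points show the log2 fold change, Dro141TX minus Maxifort, of the named genes with a symbol and an edgeR adjusted p under 0.05, and bars show its standard error. The values run from -1.30 for XTH1 to 3.19 for CHLN.

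The 10 largest qualifying rises and the 10 largest falls were all in genes without a symbol. The log2 fold changes of the rises started at 4.38, and those of the falls ran from -2.75 to -5.43. Solyc01g073755.1 (chromosome 1, 81029841 to 81032266, 5 exons) had 0 reads in every Maxifort library and 391, 178 and 216 in the Dro141TX libraries, at least 294-fold higher against a floor of 3 counts over the Maxifort group. All of its 785 reads had been placed at more than 1 position, so no read was specific to this gene. The rise may belong to another position that these reads matched. Solyc01g008620.3 (chromosome 1, 2635021 to 2636761, 2 exons), a member of the list of pathogenesis-related proteins, rose from 0, 5 and 1 reads to 79, 120 and 340, a log2 fold change of 6.67 (SE 0.92, edgeR adjusted p = 0.00422), which was 8.52 without Maxifort replicate 2 and 5.66 without Dro141TX replicate 3. Solyc11g066390.2 (chromosome 11, 52456888 to 52464078, 9 exons) fell from 56.7 ± 10.7 to 1.29 ± 0.283 CPM, a log2 fold change of -5.43 (SE 0.27, edgeR adjusted p = 1.75e-05). Solyc08g074620.2 (chromosome 8, 58865793 to 58877981, 2 exons), in the jasmonate and wound list, fell from 754, 232 and 683 reads to 15, 22 and 11, a log2 fold change of -4.90 (SE 0.43, edgeR adjusted p = 0.000582).

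Several measures of the libraries moved with the rootstock, beside each of these gene groups. Intron reads made up 5.68% ± 0.323 of gene reads on Maxifort and 8.29% ± 1.78 on Dro141TX, and reads outside genes 23.2% ± 4.97 and 39.0% ± 10.8 (exact permutation p = 0.1 for both, 2-sided, the smallest possible with n = 3). Maxifort replicate 2 lay nearest to Dro141TX on the first principal component, and Dro141TX replicate 2 nearest to Maxifort. The count of 2172 called genes was 464 without Maxifort replicate 1, 384 without Maxifort replicate 3, 1273 without Dro141TX replicate 1, 1075 without Dro141TX replicate 3 and 2406 without Maxifort replicate 2. On log2(RPKM + 0.1) with limma, whose median over all genes was -0.35, 346 genes were higher and 1348 lower. CYP707A1, FLACCA, PSBR, OPR3 and CYP lost their calls there, as did LCA1, whose log2 fold change was then -1.04. Of the 24 called genes named above, 11 passed without Maxifort replicate 1 and 9 without Maxifort replicate 3.

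**Figure D3:**
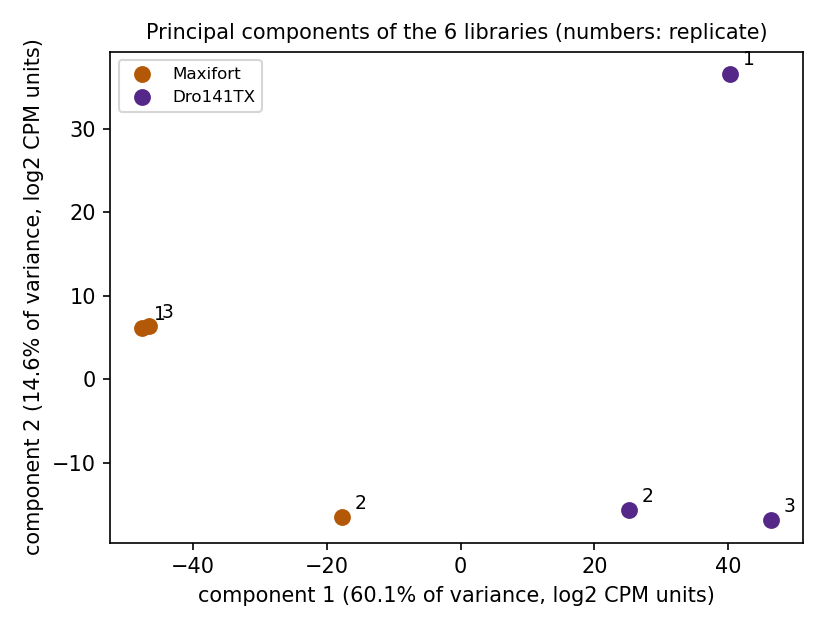
Points show the 6 libraries on the first principal components of their log2 CPM values, with the replicate number beside each point. Component 1 held 60.1% of the variance and placed the Maxifort libraries at -47.6, -17.7 and -46.6 and the Dro141TX libraries at 40.3, 25.2 and 46.4.

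The next comparison asked whether lists of related genes moved together, with defence in view because the series concerns rootstock-induced resistance of the scion to tobacco mosaic virus. Conserved housekeeping genes were lower on Dro141TX: 4 of 12 fell, 0 rose, and 7 were lower when adjusted over the list alone, with 11 of 12 log2 fold changes below 0 and a median of -0.58. The limma camera test gave an adjusted p of 0.00700 for this list, and an adjusted p = 0.429 with an estimated correlation. The list kept its direction in each of the 12 other settings run, while the intron share and the share outside genes moved with the groups as above. No other of the 6 lists passed with camera.

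Over all tested genes 20.8% were called, against which the counts in the defence lists can be set. Of 10 pathogenesis-related genes in the files only Solyc01g008620.3 had enough reads for the test, and the chitinase genes CHI3 and CHI9 had 0 reads in each of the 6 libraries, which allows up to 0.0730 CPM over all of them for counting error only. In salicylic acid and immune signalling 1 of 6 tested members rose, by 2.23 on the log2 scale (SE 0.47), 5 did not pass, and 2 were higher when adjusted over the list alone (camera adjusted p = 0.512). RNA silencing, the plant's defence against viral RNA, had 1 of 14 members higher (0.81), 2 lower (-0.93 and -0.80) and 11 not passing, with 2 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.185). Of 4 tested tobamovirus host factors, genes that such viruses need or that block them, 0 passed with edgeR, also when adjusted over the list alone, and their log2 fold changes ran from -0.75 to 0.31.

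In the jasmonate and wound list 2 of 8 members rose, OPR3 by 0.75 and another by 0.88, and 1 fell, Solyc08g074620.2, with 3 higher and 2 lower when adjusted over the list alone. Its median log2 fold change of 0.37 and its mean of -0.26 differ in sign, and the camera test, directed down, gave an adjusted p of 0.926. TD2, the wound-inducible threonine deaminase of this list, had 0.727 ± 0.668 and 2.23 ± 0.434 CPM (log2 fold change 1.63, SE 0.57, edgeR adjusted p = 0.0653), and passed, at 2.48, without Maxifort replicate 2. Of 7 ethylene genes 1 rose, by 0.60, also when adjusted over the list alone, and 6 did not pass, with 6 of the 7 log2 fold changes above 0. Camera gave an adjusted p of 0.185 for them, and of 0.429 with an estimated correlation. The adjusted p was 0.0248 with fry, which asks whether a list's genes move one way on balance, without comparing them with other genes. In the photosynthesis list 1 of 9 members fell (-0.79), with 0 when adjusted over the list alone (camera adjusted p = 0.926). Of 4 tested genes of phloem and reported mobile mRNAs 1 rose, by 1.70 (SE 0.26), also when adjusted over the list alone. GAI (Solyc11g011260.1), a DELLA growth repressor whose mRNA is known to move through the phloem, had 155 ± 17.6 and 123 ± 17.3 CPM, a log2 fold change of -0.33 (SE 0.18) that did not pass (edgeR adjusted p = 0.202).

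The last comparison counted which tomato genes were detected, with at least 10 uniquely placed reads in a library. Maxifort libraries held 10045, 9842 and 10565 such genes and Dro141TX libraries 10327, 10004 and 9777, means of 10151 ± 373 and 10036 ± 276 (2-sided exact permutation p = 0.6, n = 3). All 3 Maxifort libraries shared 9283 genes, all 3 Dro141TX libraries 9139, and all 6 libraries 8618. Detection in every Dro141TX library and no Maxifort library held for 91 genes, among them NAP1, TD2 and Solyc01g008620.3, and the reverse for 98, among them the fructokinase gene FRK2. The balance depended on the setting, with 131 for Dro141TX and 55 for Maxifort at equal depth and 45 and 150 at an RPKM of at least 1. The constant of RPKM makes that limit harder to reach on Dro141TX. Dro141TX replicate 3 had the fewest reads on genes, which lowers detection on Dro141TX at a fixed number of reads. Of the 91 and 98, 72 and 39 also passed the edgeR test. Every one of the 189 had at least 1 read in the other group, and FRK2, with 1.88 ± 0.382 and 1.29 ± 0.437 CPM, did not pass the test.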

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

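Of the tests reported in this part, those on exon reads only, the exon-length trend, the splits of the called genes, the source of photosynthesis reads, a wrong label and the rescaled fractions were chosen after the result was seen. Reads outside the listed tomato genes, taken as the RPKM constant less the gene reads, are held by no gene count. Their share of reads on the tomato genome was 19.4%, 28.8% and 21.4% in Maxifort replicates 1, 2 and 3. It was 28.9%, 50.4% and 37.6% in Dro141TX replicates 1, 2 and 3. These reads drew attention as data that the gene tests leave out.

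The number of called genes, 2172, was weighed first. Intron reads, more frequent on Dro141TX, were at most 10.3% of gene reads in a library, and 2091 genes were called on exon reads only. The intron reads themselves are thus argued against as its whole cause. Whatever raised the intron share could also have changed exon reads, which this test cannot show. A bias by exon length is argued against as the whole cause too, with 2233 called once that trend was removed. Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real one, gave as many calls, and the highest of the others gave 0, but 10 splits are too few for a share under 0.05. The rootstock, and any difference in leaf state or handling that went with it, stay open and were not tested.

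The lead of photosynthesis genes among tomato-placed reads has at least a pair of candidate explanations. Leaf reads of the scion itself, placed on conserved tomato genes, could give it, and so could rootstock transcripts that moved. The 3 RBCS genes held 17.2277% of gene reads on Maxifort and 17.0553% on Dro141TX, which either would allow. They cannot be told apart, because the files give no sequence or mismatch count. The series also holds no library of ungrafted or self-grafted Nicotiana benthamiana to show how many scion reads fall on these genes.

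Maxifort replicate 2 lay between the other Maxifort libraries and the Dro141TX libraries. On genes called without it, its place between the group means (0 at the other Maxifort libraries, 1 at Dro141TX) had a median of 0.281 for 1197 genes higher on Dro141TX and 0.524 for 1209 lower genes. Dro141TX RNA mixed in would give both sets the same place if the group means were free of selection. The difference was -0.2432 (bootstrap 95% interval -0.273 to -0.214), and -0.263 after rescaling the library on 1314 little-changed genes. However, the genes were called on the same libraries that set the places 0 and 1. Such a choice tends to overstate the mean of the higher group, which can part the sets in this direction. This test therefore cannot decide on mixing. A Dro141TX library with a wrong label would sit near 1, and the median over all was 0.3957 (0.379 to 0.409), which argues against a wrong label. Dro141TX replicate 2 in turn lay nearest to Maxifort on the first principal component, at 25.2 against 40.3 and 46.4. Maxifort replicate 2 and Dro141TX replicate 2 each had the highest intron share of their group, 5.98% and 10.3%. Each also had the highest share outside genes, 28.8% and 50.4%. Neither the test of mixing nor that of a wrong label bears on this likeness. Handling of the sample and a difference between grafts stay open, untested, and mixing stays open as well.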

How the results depend on the processing

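All 24 genes named as called kept their direction under each of the 19 alternatives that gave them a value. Without Maxifort replicates 1, 2 and 3, 13, 2 and 15 of them lost their call, without Dro141TX replicates 1, 2 and 3, 7, 5 and 7, and with either RPKM setting 6. NCED2 lost it whichever library was left out, LCA1, CAB13 and PGH1 in 5 of these 6 fits, and CITRX, MSI1 and OPR3 in 4. psaJ and CYP lost it with the exon-length trend removed, LCA1 with DESeq2 and without a filter, LCA1 and PGH1 with library size only, and NCED2 at a mean of 50 reads and at equal depth. On unique reads NCED2, SAM3 and CAB13 lost it, and CYP707A1, FLACCA, PSBR, OPR3, CYP and LCA1 on both RPKM scales. NAP1 and LCA1 had too few reads to be tested at a mean of 50, and Solyc01g073755.1 had none to test on unique reads. Outside the left-out libraries, the called total ran from 1587 with a replicate block to 3191 at an adjusted p under 0.1, except for 403 (230 higher, 173 lower) under 0.01, where the stricter threshold is the cause. Leaving out each library gave 384 to 2406 called genes, 209 to 1197 higher and 175 to 1209 lower. DESeq2 called 2189 genes. Genes higher on Dro141TX numbered 346 on log2(RPKM + 0.1) and 383 on log2(RPKM + 1), against 1348 and 1423 lower. These settings change the test, the filter, the reads and the scaling together, so the cause was not tested. The median over all genes was then -0.35 and -0.26. On these scales the log2 fold change of RBCS-1 was -0.012 in both, and RBCS-2A of -0.32 in both. The log2 fold change of RBCS-2A was also negative with the exon-length trend removed (-0.0619) and ran from -0.14 to 0.20 as each library was left out. The cause of the changes of RBCS-2A outside the RPKM scales was not tested.

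Same-numbered libraries had correlations of deviations from their group means of 0.0777, 0.000710 and -0.130. These values gave no sign of pairing by replicate number. Differently numbered libraries were not compared in this way, so pairing is not excluded. The replicate block called 829 genes higher and 758 lower, and left LCA1, CITRX, MSI1, OPR3, NCED2 and PGH1, 6 of the 24 named genes, short of the threshold. It turned the jasmonate list's direction up (adjusted p = 0.992). Without Maxifort replicate 1, Maxifort replicate 2, Dro141TX replicate 1 or Dro141TX replicate 2 that list also pointed up, with an adjusted p of 0.466 to 0.964 over all left-out libraries. The photosynthesis list pointed down without Maxifort replicate 1, Maxifort replicate 3 or Dro141TX replicate 2 (adjusted p = 0.745, 0.997 and 0.415), and the range over all left-out libraries, either direction, was 0.369 to 0.997. The other lists ran from 0.0507 to 0.335 (RNA silencing), 0.124 to 0.335 (ethylene), 0.335 to 0.878 (salicylic acid) and 0.00409 to 0.0187 (housekeeping). Ethylene passed with fry (0.0248) and housekeeping did not with an estimated correlation (0.429), and the cause was not tested.

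At 50 reads or more, 5762 genes were found in all Maxifort, 5464 in all Dro141TX and 5127 in all libraries, as a stricter limit must lower them. Maxifort alone had 53 genes at 1 read, 150 at an RPKM of 1 and 55 at equal depth, and Dro141TX alone 66, 45 and 131. Without a library, the counts ran from 122 to 260 for Maxifort alone, 112 to 168 for Dro141TX alone, 9283 to 9777 and 9139 to 9549 for all of each group, and 8674 to 8833 for all libraries, and the cause of the moves was not tested. On summed TPM, shares on Maxifort and Dro141TX were 0.0136% and 0.0150% (salicylic acid), 0.0223% and 0.0168% (RNA silencing), 0.00930% and 0.0135% (ethylene), 28.0% and 27.4% (photosynthesis), 0.470% and 0.312% (housekeeping), 41.0% and 40.1% (10 genes with most reads) and 27.0% and 26.5% (RBCS), and the cause was not tested. The planned test without ribosomal RNA was not run, because the files name no such genes. Depth limits low genes: a count of 0 allows up to 0.591 CPM in the smallest library.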

Other observations

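Of the 33925 listed genes, 18419 had a read in some library, and some symbols had few or none. Of 8 genes of pollen, flower and fruit, 5 had 0 reads in all libraries, among them LAT52 and LAT56 of pollen, and 7 had fewer than 10 reads in total. Of 10 defence and resistance symbols, 7 had fewer than 10 reads in total, with PTI5 and PTI6, ethylene-response factors that bind the kinase Pto, at 0 and CITRX at 932. In the jasmonate group the allene oxide synthase gene AOS1 had 6 reads in total and OPR3 17230. In the ethylene group the ethylene-forming oxidase genes ACO1 and ACO4 had 14 and 9, and SAM3 25698. These genes were picked for this paragraph after their values were seen.

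Of the 2172 called genes, 62 had under 50% of their reads uniquely placed, and 17 had 0 unique reads, Solyc01g073755.1 among them. In 4216 tested genes, 40.4%, the groups did not overlap, against 10% by chance.

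Of the tests here, both were set before their result was seen. A hypothesis that called genes cluster on some tomato chromosomes, as introgressed segments of a rootstock might give, was tested over the 12 chromosomes. The called share ran from 18.7% on chromosome 10 to 22.7% on chromosome 9, and a permutation of calls over genes gave p = 0.6. The values thus gave no backing to clustering by whole chromosome. A share per chromosome cannot show shorter segments, so introgressed segments were not tested. For the genes found in all libraries of a group and in none of the other, only 1 of the 10 splits, the real one, gave as many as 189, and the highest other gave 84. With 10 splits a share under 0.05 is out of reach.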
